A study of Bos taurus with 18 samples.

How the data were processed

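Total RNA from 4 compartments of the cattle ovary was hybridised to 18 single-colour expression arrays. Per the labels, ovaries came from non-pregnant cows at an abattoir. The theca layer was dissected from healthy antral follicles under 5 mm in diameter, with 1 follicle and 1 animal behind each of 6 arrays. The tunica albuginea and both kinds of stroma (interstitial, and close to follicles) were cut by laser from stained 10 µm sections of cortex, with 4 arrays each, and each of these arrays held RNA pooled from different animals. Per the labels' protocols, RNA of theca was extracted with a column kit (RNeasy mini) and RNA of the laser-captured tissue with a kit for very small samples (RNAqueous-Micro). All RNA was then amplified with the same whole-transcriptome system, starting from picogram amounts, and labelled with biotin. Theca and laser-captured tissue therefore differed in collection, pooling and RNA kit as well as in compartment, and these cannot be told apart in any comparison with theca. The number of animals in a pool, and whether pools shared animals, are not given in the sources used here. The p-values among laser-captured compartments rest on 1 spread estimated over all 18 arrays, the single-animal theca arrays included. They are too small if pools of the same compartment shared animals, and can be too large if pools of different compartments did.

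The deposited values are log2 signals. Per the submitters' processing notes they were made with RMA (background correction, quantile normalization and summary of probes) and Partek 6.5. The table holds 26773 transcript clusters, each summarising the probes of 1 transcript region, with values from 1 to 13.2 rounded to 1 decimal. Every array had a median of 4.1. Rounding limits a single value to steps of 0.1, and quantile normalization removes any difference in total signal between compartments, so a change common to most genes would not be seen. A low log2 value can be background, since the table gives no detection call. The number of arrays limits the precision.

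Groups were taken from the sample titles and the compartment labels. A further label called every sample thecal tissue and was not used. Replicates within a group held identical values at 9.12% to 14% of clusters, as expression values with 1 decimal give, and no pair was treated as a repeat. Genes were named through the array's annotation table, which listed 19145 of the clusters. Of these, 18457 carried 1 gene symbol and 688 several, and clusters with several symbols or no entry (7628) were tested but not named. Entrez identifiers of 17996 clusters were found in the RefSeq gene table, and no symbol needed an update. Where a gene had more than 1 cluster (401 of 18010 genes), the cluster with the highest mean over all arrays stood for it. Control spots cannot be told from the numeric cluster identifiers, so all clusters were tested.

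Differences were tested with limma 3.58.1 in R 4.3.3 on the log2 values as deposited, with 1 mean per compartment over all 18 arrays, empirical Bayes moderation and two-sided p-values. Benjamini-Hochberg adjustment ran over all clusters, and an adjusted p below 0.05 counted as a change. The comparisons were the 6 pairs of compartments, theca against the mean of the 3 laser-captured compartments, and an F test over all 4. SE is the moderated standard error of a log2 difference, and SD is the spread of arrays within a compartment. Replicate numbers in the labels were not treated as pairing, because the deviations of same-numbered arrays from their group means did not correlate above 0.1 in every pair of any 2 compartments.

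A total of 21 gene lists with 587 members, 496 of them measured, were fixed before the data were examined, together with the tests, the alternatives and the rule for named genes. The lists were steroidogenesis, cholesterol biosynthesis and uptake, fibrous extracellular matrix, basement membrane, TGF-beta family signalling, WNT signalling, hedgehog response, steroid hormone receptors, retinoid metabolism, cell cycle, immediate early and stress genes, cytosolic ribosomal proteins, oxidative phosphorylation, and markers of endothelial cells, smooth muscle and pericytes, immune cells, granulosa cells, surface epithelium, oocytes, nerve and Schwann cells, and red blood cells. Each list was tested in the 7 comparisons with camera (limma), which asks whether its genes lie higher or lower than all other genes, with a preset correlation between genes of 0.01 and adjustment over the 147 tests. The same test with the correlation estimated from the arrays, and fry, were run beside it. Of the 72 list calls made by camera, 8 held with an estimated correlation: oxidative phosphorylation in theca against interstitial stroma, tunica albuginea and the mean, WNT signalling in theca against tunica albuginea and the mean, retinoid metabolism in both comparisons of tunica albuginea with laser-captured stroma, and fibrous extracellular matrix in tunica albuginea against stroma close to follicles. Genes at least 4-fold higher in theca than in 1 laser-captured compartment formed a further set, which was tested between the other pair of compartments, so that the set was chosen on arrays outside the tested pair.

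Named genes are, per comparison, up to 12 with the largest positive and 12 with the largest negative difference among genes past the threshold, with no overlap of values between the groups and with the higher group above the median signal. To these were added up to 4 members of each list with the largest differences past the threshold (or the 2 largest as values where fewer than 2 passed) and a fixed set of marker genes. STAR and ACTA2 belonged to that set and are not reported, because their clusters carried several symbols. Other genes named were chosen after their values were seen, and this is said where they appear.

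The test was checked on simulated arrays with the means and spread of the real clusters, 200 of 26773 clusters changed and values rounded to 1 decimal. For theca against the mean of the laser-captured compartments it recovered 29.9%, 83.6% and 100% of clusters changed by 0.5, 1 and 2 log2 units. For stroma close to follicles against interstitial stroma it recovered 11.9%, 70.1% and 98.5% of clusters changed by 0.5, 1 and 2 log2 units. There were 8 false calls among 128. The real comparison called 9 clusters, which sets a stricter cut-off than 128 calls, so these shares can be too high for it. Each cluster was simulated with the same spread in every compartment. In simulated arrays without change, 6 of 147 list tests fell under 0.05 before adjustment. Genes were simulated independently of each other, while correlations estimated from the real arrays reached 0.726 (cell cycle). The simulation therefore cannot check the list tests where members move together. A list raised by 0.5 in tunica albuginea over interstitial stroma was called by camera over 18010 genes. Alternatives covered re-normalization, median centring, a filter on the 40% dimmest clusters, the prior, moderation, array weights, the arrays in the fit, the replicate number as a block, 1 cluster per gene, a 2-fold minimum and leaving out each array. Figures were drawn with matplotlib 3.10.9.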

Results

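Gene expression was measured in 4 compartments of the bovine ovary: the theca of small antral follicles (the steroid-producing layer around the follicle wall, 6 arrays), interstitial stroma (4 arrays), stroma close to follicles (4 arrays) and the tunica albuginea (the collagen-rich layer under the ovarian surface, 4 arrays). The comparisons asked how these layers of stroma differ in their transcripts, and whether stroma lying beside follicles already resembles theca. Every array had a median log2 signal of 4.1, and the 75th percentile lay between 5.6 and 5.8. Mean correlations of an array with the others of its compartment ranged from 0.956 to 0.974. The first principal component held 45.6% of the variance and set theca (scores 55.2 to 83.1) apart from all laser-captured arrays. The second component held 8.6% and separated tunica albuginea (29.5 to 40.3) from stroma close to follicles (-41.3 to -16), with interstitial stroma between them (-18.4 to 0.0441).

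**Figure D1:**
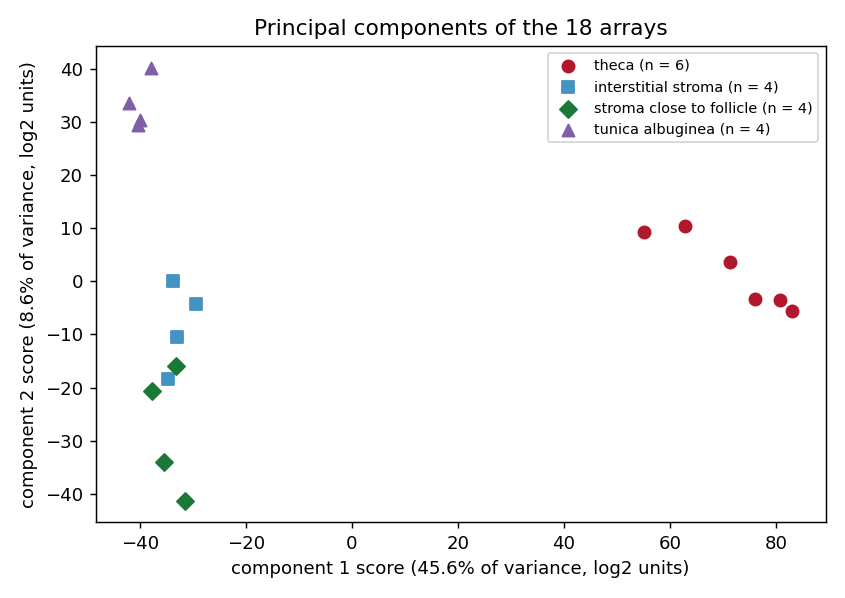
Scores of the 18 arrays on the first principal component (x axis, 45.6% of the variance) and the second (y axis, 8.6%), in log2 units, with 1 point per array and the compartment shown by colour and shape. The 6 theca arrays lie between 55.2 and 83.1 on the first component, and all laser-captured arrays lie below 0 on it.

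The theca expressed the genes of androgen synthesis far above the other compartments. INSL3, a peptide hormone of steroid-producing gonadal cells, stood at 10.87 ± 0.30 (SD, n = 6) in theca against 3.48, 3.62 and 3.15 in interstitial stroma, stroma close to follicles and tunica albuginea, a difference from their mean of 7.45 ± 0.15 (SE, limma adjusted p = 4.1e-16). CYP11A1, which makes pregnenolone from cholesterol, was higher by 6.77 ± 0.21 log2 units, the luteinizing hormone receptor LHCGR by 6.38 ± 0.13, HSD3B1 by 6.24 ± 0.15 and CYP17A1, the enzyme that leads to androgens, by 5.61 ± 0.35, with adjusted p at or below 9.3e-10. GSTA1, a glutathione transferase, was higher by 6.46 ± 0.22 and also differed among the laser-captured compartments. The other leading genes were OTOS (6.25), the chemokine CXCL14 (5.78), ADAMDEC1 (4.88), KCNIP1 (4.82), MAL2 (4.77) and S100A2 (4.57). INSL3, CYP11A1, LHCGR, HSD3B1, CYP17A1, OTOS, CXCL14 and KCNIP1 lay below the median signal of 4.1 in all 3 laser-captured compartments, and ADAMDEC1, MAL2 and S100A2 in some of them. A difference from a group below 4.1 is a lower limit where that signal is background, here and in every other comparison, and the order of such differences carries no weight. In the other direction, SFRP4, a secreted WNT antagonist, had a log2 difference of -5.69 ± 0.15 (adjusted p = 5.1e-15), with 3.78 in theca and 9.15 to 9.88 in the other compartments. HOPX (-4.89; 3.95 in theca), NUPR1 (-4.85), FAIM2 (-4.77), MUSTN1 (-4.57), the peptidase ENPEP (-4.45), OPCML (-4.42), the nuclear receptor NR4A1 (-4.08), MDGA2 (-3.96), the prostaglandin E synthase PTGES (-3.87), MIR99A (-3.83) and the complement protease C1S (-3.77) followed. None of the values of these genes in theca overlapped with those in the laser-captured arrays.

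In the steroidogenesis list, 12 of 20 measured genes were higher in theca and 4 lower, with the same counts adjusted over the list alone (median 0.86). The steroidogenesis test gave adjusted p = 5.7e-05 by camera and adjusted p = 0.091 with an estimated correlation. Of 15 genes of cholesterol biosynthesis and uptake, 13 rose and none fell, also when adjusted over the list alone, led by EBP (2.33 ± 0.26), NSDHL (2.16 ± 0.26), MSMO1 (2.15 ± 0.30) and SQLE (2.01 ± 0.35). The cholesterol test gave adjusted p = 1.9e-05 by camera and adjusted p = 0.3 with an estimated correlation. Oxidative phosphorylation genes, which encode the respiratory chain and ATP synthase, were higher for 63 of 69 members, and none was lower. Adjusted over the list alone there were 63 as well, the median was 0.89, and the call held with an estimated correlation. The oxidative phosphorylation test gave adjusted p = 2.5e-23 by camera and adjusted p = 0.045 with an estimated correlation. ATP5MC1 (2.42 ± 0.32), NDUFA11 (1.71 ± 0.16), ATP5ME (1.59 ± 0.09) and NDUFA5 (1.53 ± 0.12) showed the largest differences. Cell cycle genes were higher for 23 of 28 members (25 adjusted over the list alone) and lower for none, with a median of 1.8. KIF11 (4.18 ± 0.29), the proliferation marker MKI67 (3.94 ± 0.30), TPX2 (3.87 ± 0.27) and UBE2C (3.64 ± 0.25) led this list. The cell cycle test gave adjusted p = 1.4e-12 by camera and adjusted p = 0.3 with an estimated correlation. The list mean varied more among theca arrays (6.57 ± 0.79, SD, n = 6) than in interstitial stroma (4.64 ± 0.05, SD, n = 4). Of 37 cytosolic ribosomal protein genes, 12 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.11, and RPL39 (0.82 ± 0.12) and RPLP0 (0.79 ± 0.11) were the largest increases. The ribosomal protein test gave adjusted p = 0.017 by camera and adjusted p = 0.56 with an estimated correlation. Against tunica albuginea alone the ribosomal list was not called (camera adjusted p = 0.063).

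**Figure D2:**
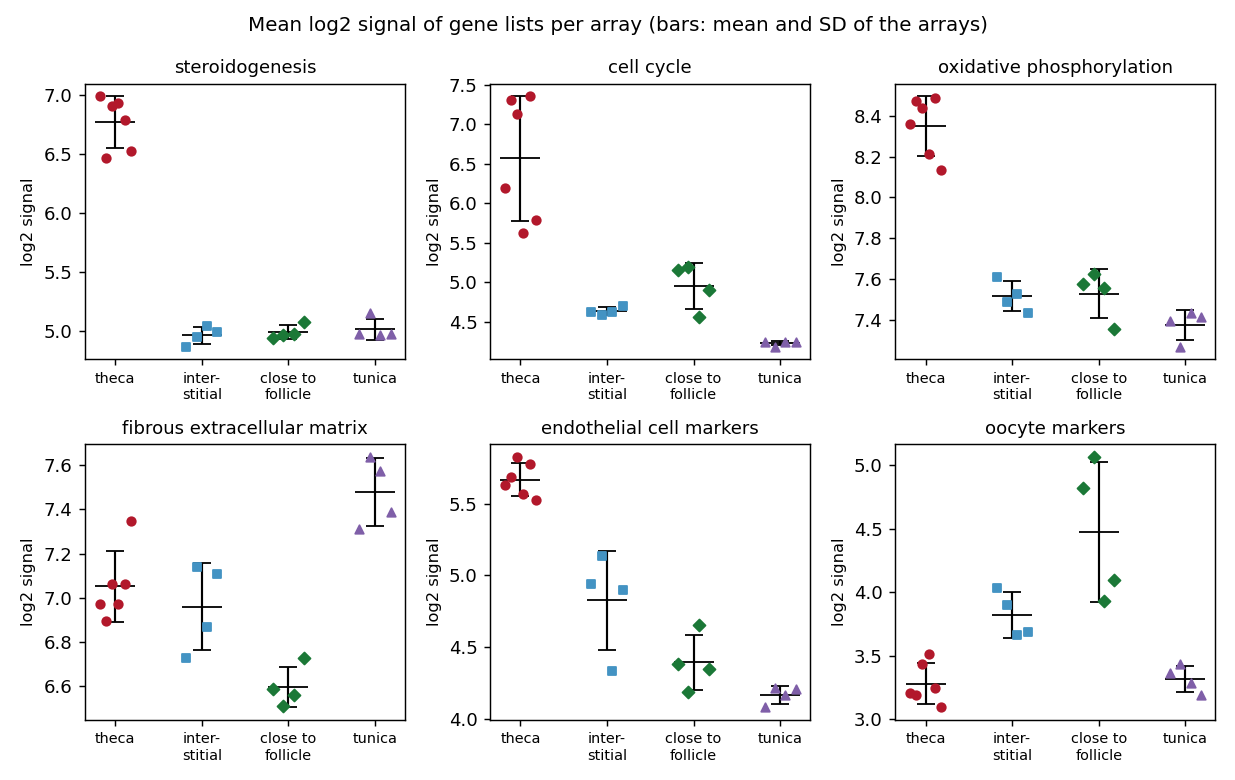
Mean log2 signal (y axis) of the measured members of 6 gene lists in each array, by compartment (x axis), with 1 point per array and bars for the mean and SD of the arrays (n = 6 for theca, n = 4 for the others). Steroidogenesis, cell cycle and oxidative phosphorylation means are higher in theca (6.77, 6.57 and 8.35), fibrous matrix is at 7.48 in tunica albuginea, and oocyte markers are at 4.48 in stroma close to follicles.

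Cell type markers also moved with theca. Endothelial markers were higher for 19 of 24 genes and lower for 1 (20 and 1 adjusted over the list alone), among them PTPRB (3.22 ± 0.19), PECAM1 (2.86 ± 0.22), CDH5 (2.75 ± 0.29) and the VEGF receptor KDR (2.16 ± 0.22), and VWF rose by 1.49 ± 0.17. The endothelial test gave adjusted p = 3e-09 by camera and adjusted p = 0.074 with an estimated correlation. Basement membrane genes divided, with 12 of 21 higher and 5 lower by both adjustments, over all genes and adjusted over the list alone: LAMA4 (2.74 ± 0.22), NID2 (2.13 ± 0.19) and LAMB1 (1.83 ± 0.10) rose and LAMA3 (-2.18 ± 0.19) fell. The basement membrane test gave adjusted p = 0.018 by camera and adjusted p = 0.3 with an estimated correlation. Smooth muscle and pericyte markers were lower for 11 of 20 genes and higher for 5 (12 and 5 adjusted over the list alone). The contractile genes MYH11 (-2.30 ± 0.16), MYOCD (-2.27 ± 0.22) and CNN1 (-2.15 ± 0.26) fell, while the pericyte gene RGS5 rose by 3.15 ± 0.37. The smooth muscle test gave adjusted p = 0.033 by camera and adjusted p = 0.55 with an estimated correlation. That list was not called against tunica albuginea alone (camera adjusted p = 0.13). Immune markers rose for 10 of 25 genes, also adjusted over the list alone, including C1QA (1.5 ± 0.27), CTSS (1.43 ± 0.21) and CD163 (1.37 ± 0.13), with PTPRC at 0.33 ± 0.24 (adjusted p = 0.28) not passing. The immune test gave adjusted p = 0.0038 by camera and adjusted p = 0.53 with an estimated correlation. Immune markers were called against stroma close to follicles (14 higher; camera adjusted p = 8.5e-06, lost at adjusted p = 0.3 with an estimated correlation), but not against interstitial stroma (5 higher; camera adjusted p = 0.1) or tunica albuginea (7 higher; camera adjusted p = 0.063). Granulosa cell markers were higher for 9 of 14 genes and lower for 2 by both adjustments, over all genes and adjusted over the list alone. FST (3.47 ± 0.14), INHA (3.11 ± 0.17) and INHBA (2.88 ± 0.25) rose, FSHR rose by 1.12 ± 0.27, and CDH2 fell (-1.67 ± 0.44). The granulosa test gave adjusted p = 0.0074 by camera and adjusted p = 0.12 with an estimated correlation. Oocyte markers were lower in theca for 9 of 15 genes, also adjusted over the list alone, with DAZL at -2.03 ± 0.25 and ZP3 at -1.48 ± 0.27. The oocyte test gave adjusted p = 0.013 by camera and adjusted p = 0.56 with an estimated correlation. Against tunica albuginea alone the oocyte list was not called, with 1 gene higher (camera adjusted p = 0.91) and means of 3.28 in theca and 3.32 in tunica albuginea.

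The fibrous matrix list did not shift as a whole (median 0.05, camera adjusted p = 0.9), yet 17 of its 42 genes were higher and 17 lower in theca (17 and 18 adjusted over the list alone). ASPN (4.09 ± 0.18), OGN (3.55 ± 0.21) and FBLN5 (3.53 ± 0.19) rose, as did COL3A1 (1.14 ± 0.16), and the proteoglycan PRELP fell (-3.60 ± 0.18). COL1A1 was higher than the mean by 0.78 ± 0.18, but stood at 8.63 in theca against 9.05 in tunica albuginea (-0.42 ± 0.23, adjusted p = 0.18). WNT signalling genes were lower in theca for 18 of 35 members and higher for 3, by both adjustments (over all genes and adjusted over the list alone). SFRP4, WNT5A (-3.15 ± 0.23), the WNT-enhancing ligand RSPO3 (-2.95 ± 0.34) and NKD1 (-1.67 ± 0.13) fell. The WNT test gave adjusted p = 0.00084 by camera and adjusted p = 0.045 with an estimated correlation. Of 35 genes of TGF-beta family signalling, 15 fell and 5 rose (18 and 6 adjusted over the list alone), with ID2 (-2.73 ± 0.19), BAMBI (-2.34 ± 0.15), LTBP3 (-2.12 ± 0.11) and TGFB2 (-2.0 ± 0.15) the largest. The TGF-beta test gave adjusted p = 0.0066 by camera and adjusted p = 0.34 with an estimated correlation. Immediate early and stress genes fell for 12 of 25 members and rose for 3 by both adjustments (over all genes and adjusted over the list alone), with EGR1 (-2.60 ± 0.33), JUN (-1.87 ± 0.18) and FOS (-1.77 ± 0.37) among them. The immediate early gene test gave adjusted p = 0.042 by camera and adjusted p = 0.56 with an estimated correlation. It was not called against stroma close to follicles alone (camera adjusted p = 0.14).

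The hedgehog response list was not called in theca (camera adjusted p = 0.42), and its median (-0.1) and mean (0.59) differed in sign, with the test pointing up. By both adjustments, over all genes and adjusted over the list alone, 5 of its 11 genes rose and 5 fell. The pathway targets PTCH1 (3.47 ± 0.17), HHIP (3.34 ± 0.15) and GLI1 (1.39 ± 0.14) rose, and the co-receptor BOC fell (-1.52 ± 0.11). Retinoid metabolism had a median of -0.37, a mean of 0.12 and a downward test (camera adjusted p = 0.74), with 4 of 14 genes higher and 6 lower (4 and 8 adjusted over the list alone). ALDH1A1 (3.81 ± 0.23) and ALDH1A2 (2.73 ± 0.19), which make retinoic acid, rose, and RBP4 (-2.28 ± 0.16) and the retinol transporter STRA6 (-1.71 ± 0.24) fell. STRA6 passed against tunica albuginea alone and not against interstitial stroma or stroma close to follicles. Among 8 steroid hormone receptors, 2 rose and 3 fell (2 and 4 adjusted over the list alone), with NR3C2 at -2.21 ± 0.17 and the oestrogen receptor ESR1 at -2.0 ± 0.21 (camera adjusted p = 0.47 for the list). Surface epithelium markers (5 higher and 4 lower of 18; median -0.01, mean 0.21), nerve and Schwann cell markers (2 higher and 2 lower of 11; median -0.05, mean 0.04) and red blood cell markers (2 higher of 9, and 1 adjusted over the list alone; median -0.01, mean 0.09) were not called, and in each the median and mean differed in sign while the test pointed up.

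Over all 26773 clusters, 11206 (41.9%) differed between theca and the mean of the laser-captured compartments, 5256 higher and 5950 lower, and 2598 of them by at least 2-fold (1571 higher, 1027 lower). Against single compartments, 7747 clusters differed from interstitial stroma (3850 higher, 3897 lower), 8314 from stroma close to follicles (4131 higher, 4183 lower) and 9207 from tunica albuginea (4372 higher, 4835 lower). The balance of directions depended on the size and brightness asked for: at 2-fold, 1504 were higher and 1053 lower against interstitial stroma, 1608 and 1117 against stroma close to follicles, and 1772 and 1142 against tunica albuginea. Without the 40% dimmest clusters the higher share was 54.1%, 56% and 56.3% in these comparisons and 54.6% against the mean, in place of 49.7%, 49.7%, 47.5% and 46.9%. The F test over all 4 compartments called 9743 clusters (36.4%). INSL3, LHCGR, HSD3B1, CYP11A1 and CYP17A1 differed by at least 5.50 log2 units in each of these 3 comparisons. GSTA1 was higher in theca by 6.24 ± 0.29 against interstitial stroma and 4.82 ± 0.29 against stroma close to follicles. Against tunica albuginea, where it stood at 2.65 a level that background can give, its difference of 8.32 ± 0.29 is a lower limit. Fibrous matrix genes were lower in theca than in tunica albuginea for 20 of 42 members and higher for 10 (20 and 12 adjusted over the list alone; camera adjusted p = 0.052), led by TNC (-4.69 ± 0.42) and PRELP (-4.37 ± 0.23). Because theca was also collected by another route and extracted with another kit, these differences hold compartment and collection together.

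**Figure D3:**
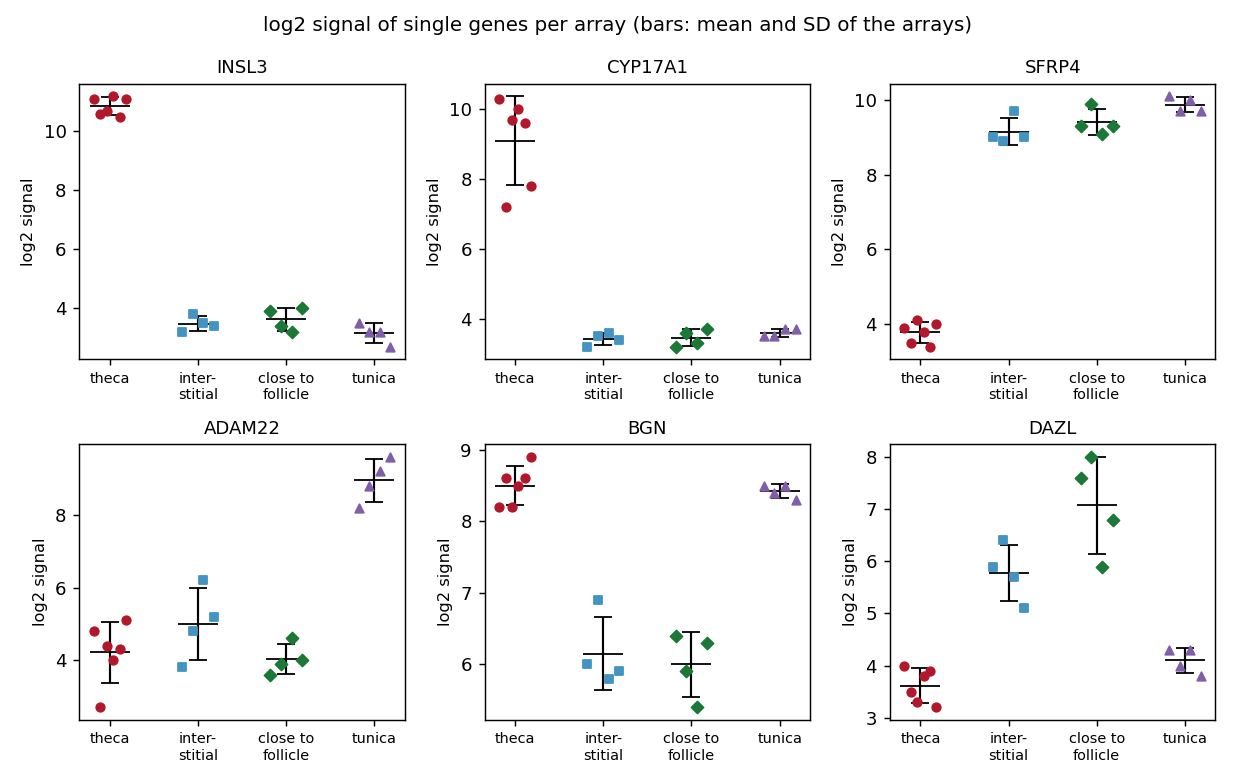
log2 signal (y axis) of 6 genes in each array, by compartment (x axis), with 1 point per array and bars for the mean and SD (n = 6 for theca, n = 4 for the others). INSL3 and CYP17A1 reach 10.87 and 9.10 on average in theca, SFRP4 lies at 3.78 there, ADAM22 is at 8.95 in tunica albuginea, BGN is at 8.43 in tunica albuginea and 8.50 in theca, and DAZL is at 7.08 in stroma close to follicles.

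ADAM22, a membrane protein of the disintegrin family, was higher in tunica albuginea than in interstitial stroma by 3.95 ± 0.48 log2 units (8.95 against 5.00, n = 4 each; limma adjusted p = 0.00031). The serotonin receptor gene HTR1D (2.92 ± 0.28), the opioid precursor PENK (2.90 ± 0.20), STRA6 (2.80 ± 0.34), PPP1R14C (2.62), EPHX1 (2.53), PTGES (2.48), the collagen COL8A2 (2.35), ATP8A1 (2.32), HOPX (2.30), the proteoglycan BGN (2.27) and SHISA9 (2.25) followed. The lowest against interstitial stroma were TUBA3E (-3.45 ± 0.38), RSPO3 (-2.75 ± 0.48), the growth factor IGF1 (-2.73 ± 0.40), PTTG1 (-2.62), the germ cell gene GTSF1 (-2.47), OSR2 (-2.32), RUNDC3B (-2.15), LHX9 (-2.12), GSTA1 (-2.07), UNC13C (-2.0), KDR (-1.95) and LAMA4 (-1.93). In total 407 clusters differed, 253 higher and 154 lower in tunica albuginea, 233 of them by at least 2-fold.

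Fibrous matrix genes were higher in tunica albuginea than in interstitial stroma for 12 of 42 members (18 adjusted over the list alone) and lower for none, among them TNC (2.25 ± 0.46), THBS1 (1.57 ± 0.31) and COL1A1 (1.48 ± 0.26), while COL3A1 did not pass (0.13 ± 0.22). The fibrous matrix test gave adjusted p = 1.7e-11 by camera and adjusted p = 0.082 with an estimated correlation. In retinoid metabolism, STRA6, DHRS3 (2.15 ± 0.27) and ALDH1A3 (1.32 ± 0.26) rose of 14 genes (5 adjusted over the list alone), and the call held with an estimated correlation. The retinoid test gave adjusted p = 0.0011 by camera and adjusted p = 0.045 with an estimated correlation. WNT signalling was called upwards, with 3 genes higher and 2 lower of 35 (6 and 2 adjusted over the list alone). WNT5A (1.40 ± 0.33) and the antagonist family member DKK3 (1.40 ± 0.20) rose, and RSPO3 and SFRP2 (-1.90 ± 0.37) fell. The WNT test gave adjusted p = 0.02 by camera and adjusted p = 0.1 with an estimated correlation. Endothelial markers fell for 5 of 24 genes (13 adjusted over the list alone), with CLDN5 (-1.63 ± 0.28), PECAM1 (-1.47 ± 0.31) and TEK (-1.40 ± 0.24) beside KDR. The endothelial test gave adjusted p = 6e-11 by camera and adjusted p = 0.065 with an estimated correlation. Smooth muscle and pericyte markers were called downwards on RGS5 (-2.78 ± 0.52) and ABCC9 (-1.68 ± 0.26), 2 of 20 genes (5 lower and 1 higher adjusted over the list alone). The smooth muscle test gave adjusted p = 0.018 by camera and adjusted p = 0.51 with an estimated correlation. Oocyte markers were lower on balance with 1 of 15 passing, DAZL (-1.67 ± 0.35) (2 adjusted over the list alone). The oocyte test gave adjusted p = 0.00017 by camera and adjusted p = 0.35 with an estimated correlation. Cell cycle genes had a median of -0.32 with 1 of 28 passing, AURKA (-1.92 ± 0.40), also adjusted over the list alone. The cell cycle test gave adjusted p = 0.00093 by camera and adjusted p = 0.65 with an estimated correlation. That correlation came from all 18 arrays, and the list varied most in theca (SD 0.79), which is outside this comparison. Its SD was 0.05 in interstitial stroma and 0.03 in tunica albuginea. The list means of these 2 groups did not overlap (4.59 to 4.70 and 4.19 to 4.25). Oxidative phosphorylation had a median of -0.12, and limma passed 0 of 69 members over all clusters and 0 adjusted over the list alone, with 11 at an unadjusted p under 0.05. The oxidative phosphorylation test gave adjusted p = 0.0024 by camera and adjusted p = 0.53 with an estimated correlation. The median (0.03) and mean (-0.05) of basement membrane genes differed in sign, and the list was not called (camera adjusted p = 0.96). The count of 407 fell to 204 when only these 2 compartments were fitted, was 215 when the replicate number was also a block (chosen after seeing the data), and lay between 219 and 477 when single arrays were left out.

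Against stroma close to follicles, ADAM22 was higher in tunica albuginea by 4.93 ± 0.48 (limma adjusted p = 1.9e-05), TNC by 3.60 ± 0.46, STRA6 by 2.80 ± 0.34, RAMP3 by 2.62, HTR1D by 2.60, COL8A2 by 2.52, the cytokine IL18 by 2.5, TRHDE by 2.48, BGN by 2.43, PENK by 2.42, EPHX1 by 2.40 and ENPP6 by 2.35. TUBA3E (-4.80 ± 0.38; adjusted p = 3.7e-06), GTSF1 (-4.40 ± 0.50), ADAD1 (-4.03 ± 0.49), GSTA1 (-3.50 ± 0.32), AURKA (-3.38 ± 0.40), PTTG1 (-3.38), PHYHIPL (-3.17), FOXR1 (-3.10), CCDC181 (-2.98), DAZL (-2.97), CHL1 (-2.95) and SAXO1 (-2.95) were lower. GTSF1, ADAD1 and DAZL are germ cell genes. In total 1017 clusters differed, 494 higher and 523 lower, and 497 by at least 2-fold.

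Fibrous matrix genes were higher in tunica albuginea for 20 of 42 members and lower for none (29 and 1 adjusted over the list alone), with COL1A1 at 2.13 ± 0.26 and THBS1 at 1.95 ± 0.31, and the call held with an estimated correlation. The fibrous matrix test gave adjusted p = 2.3e-22 by camera and adjusted p = 0.045 with an estimated correlation. Retinoid metabolism genes rose for 5 of 14 members, also adjusted over the list alone, including DHRS3 (2.08 ± 0.27), ALDH1A1 (1.58 ± 0.32) and ALDH1A3 (1.37 ± 0.26). The retinoid test gave adjusted p = 0.0011 by camera and adjusted p = 0.045 with an estimated correlation. Oocyte markers fell for 10 of 15 genes (12 adjusted over the list alone), with ZP3 (-2.60 ± 0.39), KPNA7 (-1.82 ± 0.28) and OOEP (-1.5 ± 0.35) beside DAZL. The oocyte test gave adjusted p = 3.8e-13 by camera and adjusted p = 0.071 with an estimated correlation. Cell cycle genes fell for 6 of 28 members (8 adjusted over the list alone), with CKS2 (-2.22 ± 0.47) and BUB1B (-1.70 ± 0.44) beside AURKA. The cell cycle test gave adjusted p = 5.7e-07 by camera and adjusted p = 0.5 with an estimated correlation. Immune markers were called upwards with PTPRC (1.5 ± 0.33) alone passing of 25 genes (7 higher and 1 lower adjusted over the list alone). The immune test gave adjusted p = 9.3e-06 by camera and adjusted p = 0.3 with an estimated correlation. Endothelial markers were called downwards with KDR (-1.35 ± 0.30) and TEK (-0.88 ± 0.24) passing of 24 (5 lower and 1 higher adjusted over the list alone). The endothelial test gave adjusted p = 0.023 by camera and adjusted p = 0.53 with an estimated correlation. Oxidative phosphorylation had a median of -0.1, with 1 gene higher and 2 lower of 69 (1 and 5 adjusted over the list alone). The oxidative phosphorylation test gave adjusted p = 0.011 by camera and adjusted p = 0.58 with an estimated correlation. The median and mean differed in sign for steroidogenesis (-0.06 and 0.03; the test pointed up) and surface epithelium markers (0.03 and -0.24; the test pointed down), and neither was called. The count of 1017 fell to 434 when only these 2 compartments were fitted, fell to 164 when the replicate number was also a block (chosen after seeing the data), and lay between 627 and 1022 when single arrays were left out.

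Stroma close to follicles and interstitial stroma were the most similar pair. Only 9 clusters differed, all higher close to follicles, and 2175 had an unadjusted p under 0.05. SAXO1 (2.10 ± 0.33), MAEL (1.67 ± 0.28), EPCAM (1.47 ± 0.22), CDH7 (1.42 ± 0.24), SOHLH2 (1.38 ± 0.21), ALOX15B (1.30 ± 0.21) and TNNI3 (1.30 ± 0.21) passed with adjusted p between 0.035 and 0.04 (limma, n = 4 each). MAEL and SOHLH2 are germ cell genes, and EPCAM is an epithelial adhesion molecule. CYP17A1, HSD3B1, INSL3, CYP11A1 and LHCGR lay below the median signal of 4.1 in both groups, where a low level cannot be told from background, so they do not show whether stroma beside follicles resembles theca. CYP17A1 differed by 0.03 ± 0.49, HSD3B1 by 0.10 ± 0.21, INSL3 by 0.15 ± 0.21, CYP11A1 by 0.67 ± 0.30 and LHCGR by -0.17 ± 0.19.

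Oocyte markers were called upwards close to follicles, with a median of 0.72 and list means of 4.82, 5.07, 3.93 and 4.09 in the 4 arrays. By limma 0 of 15 genes passed over all clusters, 10 passed adjusted over the list alone and 10 had an unadjusted p under 0.05, with ZP3 at 1.5 ± 0.39 and DAZL at 1.30 ± 0.35. The oocyte test gave adjusted p = 8.6e-11 by camera and adjusted p = 0.099 with an estimated correlation. Surface epithelium markers were called upwards on EPCAM, 1 of 18 genes (4 adjusted over the list alone). The surface epithelium test gave adjusted p = 0.00061 by camera and adjusted p = 0.071 with an estimated correlation. Cell cycle genes were called upwards with 0 of 28 passing limma over all clusters, 2 adjusted over the list alone and 3 unadjusted, and AURKA stood at 1.45 ± 0.40. The cell cycle test gave adjusted p = 0.0027 by camera and adjusted p = 0.65 with an estimated correlation. Immune markers were called downwards with a median of -0.55, 0 of 25 passing limma over all clusters, 9 adjusted over the list alone and 13 unadjusted, and with CD52 at -1.47 ± 0.40 and CTSS at -1.27 ± 0.30. The immune test gave adjusted p = 6e-11 by camera and adjusted p = 0.12 with an estimated correlation. Endothelial markers had a median of -0.46, with 0 of 24 passing limma, 2 adjusted over the list alone and 8 unadjusted. The endothelial test gave adjusted p = 1.3e-07 by camera and adjusted p = 0.1 with an estimated correlation. Replicate 3 of both groups went the other way: the immune mean was 4.6 close to follicles and 4.27 in interstitial stroma, and the endothelial mean was 4.65 and 4.33. Fibrous matrix genes had a median of -0.29, with 0 of 42 passing limma, 4 adjusted over the list alone and 13 unadjusted, and OGN at -1.37 ± 0.29. The fibrous matrix test gave adjusted p = 3.2e-09 by camera and adjusted p = 0.12 with an estimated correlation. Basement membrane genes had a median of -0.18, with 0 of 21 passing limma, 1 adjusted over the list alone and 4 unadjusted, and LAMA4 at -1.35 ± 0.31. The basement membrane test gave adjusted p = 0.01 by camera and adjusted p = 0.29 with an estimated correlation. Nerve and Schwann cell markers had a median of 0.07, a mean of -0.07 and a downward test, and were not called (camera adjusted p = 0.82). With only the 12 laser-captured arrays fitted, limma called 0 clusters in place of 9, and 2069 had an unadjusted p under 0.05. Leaving out single arrays gave between 0 and 152 clusters, and without interstitial stroma replicate 3 only 41.4% of 29 clusters were higher close to follicles.

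The 287 genes at least 4-fold higher in theca than in tunica albuginea did not separate stroma close to follicles from interstitial stroma. Their mean was 4.37 ± 0.13 (SD, n = 4) close to follicles and 4.33 ± 0.16 (SD, n = 4) in interstitial stroma, a difference of 0.041 (two-sided exact permutation test, p = 0.714; camera p = 0.79), and 1 of these genes, TNNI3, changed. Both means lay near the median signal of 4.1, so low expression of these genes could go unseen. Endothelial and cell cycle genes were not left out of this set. The endothelial list mean was 4.39 close to follicles and 4.83 in interstitial stroma, and the cell cycle list mean was 4.95 and 4.64. Shifts in opposite directions could offset each other in the set mean, so it cannot decide whether stroma beside follicles resembles theca. TNNI3 was at 8.17 in theca, 4.97 close to follicles and 3.67 in interstitial stroma. The 210 genes at least 4-fold higher in theca than in interstitial stroma had a mean of 4.21 ± 0.10 (SD, n = 4) close to follicles and 4.05 ± 0.04 (SD, n = 4) in tunica albuginea, a difference of 0.162. The two-sided exact permutation test gave p = 0.0286, the smallest value that 70 splits allow, and camera gave p = 0.04 (p = 0.41 with an estimated correlation). In either direction 29 of the 210 genes changed, against 881 of all 18010 genes. Cell cycle genes were not left out of this set, and their list mean was 4.95 close to follicles and 4.23 in tunica albuginea. For genes at least 2-fold and at least 8-fold higher in theca the differences from tunica albuginea were 0.065 (exact p = 0.229) and 0.036 (exact p = 0.657). The differences from interstitial stroma turned in sign for these sets, at -0.006 (exact p = 0.914) and -0.042 (exact p = 0.714).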

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

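Values of each array were compared with the others of its compartment by the gap to the nearest array as a share of the whole range, in groups of 4 or 6 arrays. Of 84 groups of list means, 5 held an array set apart in this way, and of 556 groups of gene values, 9 did. For gene values 1 rounding step of 0.1 was first taken off the gap. Chance alone sets apart about 1 in 20 groups of list means, and fewer groups of gene values. No explanation was tested for these arrays, and no biological one is given by the design.

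Among list means, theca replicate 6 had a fibrous matrix mean of 7.35, with the nearest other theca array at 7.06. Interstitial stroma replicate 4 had a mean of 6.46 for immediate early and stress genes, with the other arrays between 5.96 and 6.02. Tunica albuginea replicate 2 had a steroidogenesis mean of 5.15 with the others at 4.97, and a cell cycle mean of 4.19 with the others at 4.24 to 4.25. Stroma close to follicles replicate 1 had a mean of 6.89 for smooth muscle and pericyte markers, with the others between 6.74 and 6.76.

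Among genes, theca replicate 6 had lower CXCL14 (8.1, the others 9.2 to 9.6) and CYP11A1 (9.2, the others 10.1 to 10.2). Theca replicate 2 had lower ALDH1A1 (8.3, the others 9.1 to 9.4) and OSR2 (5.5, the others 6.6 to 7.0). NR4A1 was at 4.9 in theca replicate 3, with the others between 4.1 and 4.3. RGS5 was at 4.7 in interstitial stroma replicate 3, with the others at 7.1, and KIF11 was at 2.5 in interstitial stroma replicate 1, with the others at 3.1. ALOX15B was at 5.4 in stroma close to follicles replicate 2, with the others between 4.2 and 4.3. ADAMDEC1 was at 3.8 in tunica albuginea replicate 1, with the others at 3.1.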

How the results depend on the processing

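The replicate block fitted to only the compared compartments, and noise within the rounding step, were chosen after seeing the data; the other alternatives were planned. No named gene or list was counted as reversed. Other results did turn in direction. The uncalled difference of theca-high genes between stroma close to follicles and interstitial stroma went from 0.041 to -0.006 and -0.042 with the 2-fold and 8-fold sets. The share of clusters higher close to follicles went from 100% of 9 to 41.4% of 29 without interstitial stroma replicate 3. Of 5736 values of called genes under other settings, 5519 stayed past the threshold in the same direction and 217 no longer passed. Of 5946 values with 1 array left out, 5692 and 254 did so. Of 2604 values of genes not called, 46 passed. Of 3381 list values, 115 were lost and 46 gained. Centring each array on its median moved nothing, because all medians were 4.1, and says nothing about stability. Leaving out clusters by the ending of their identifiers was not run, because the identifiers are plain numbers.

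Asking for at least 2-fold left 2557, 2725 and 2914 clusters for theca against interstitial stroma, stroma close to follicles and tunica albuginea, 2598 against their mean and 4027 in the F test. It left 233 for tunica albuginea against interstitial stroma and 497 against stroma close to follicles. These counts are lower by construction. With only the compared compartments in the fit, tunica albuginea differed from interstitial stroma in 204 clusters and from stroma close to follicles in 434, with fewer arrays to estimate the spread. The replicate block with only the compared compartments gave 215 and 164 for these pairs. For theca it gave 5397, 5454 and 5784 against interstitial stroma, stroma close to follicles and tunica albuginea. Theca replicates 5 and 6 have no array of the same number in the other compartments, so this block takes them out of these comparisons. Beyond this, the cause was not tested. Deviations of tunica albuginea and interstitial stroma arrays from their group means correlated at 0.095, 0.097, 0.129 and 0.145 between equal replicate numbers and at most at 0.013 between unequal ones, so pools of these compartments may share animals. The replicate block over all arrays gave 333 clusters for this pair.

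The 9 clusters higher close to follicles than in interstitial stroma depended on most choices. Limma gave 3 without the dimmest clusters, 14 with a trend and robust prior, 5 with the replicate block and 29 with 1 cluster per gene. It gave 0 without moderation (2133 at an unadjusted p under 0.05), 0 with only these compartments (2083), 0 with the replicate block and only these compartments (1997) and 0 with only the 12 laser-captured arrays (2069). Leaving out single arrays gave 0 to 152: 0 without interstitial stroma replicate 2 (1921 unadjusted), interstitial stroma replicate 4 (1846) or stroma close to follicles replicate 2 (1912), 2 without replicate 1 of either, 29 without interstitial stroma replicate 3 (41.4% of them higher close to follicles), 14 without stroma close to follicles replicate 4 and 152 without stroma close to follicles replicate 3. The cause was not tested.

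Leaving out single arrays gave 6508 to 7749 clusters for theca against interstitial stroma, 7060 to 8128 against stroma close to follicles, 8027 to 9056 against tunica albuginea, 10047 to 11138 against the mean and 8480 to 9788 in the F test. Tunica albuginea differed from interstitial stroma in 219 to 477 clusters: 219, 246 and 258 without interstitial stroma replicates 1, 2 and 4, and 224 without tunica albuginea replicate 3. It differed from stroma close to follicles in 627 to 1022: 652 and 645 without stroma close to follicles replicates 1 and 2, and 627 without tunica albuginea replicate 3.

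The excess of 0.162 of theca-high genes close to follicles over tunica albuginea no longer passed camera with an estimated correlation (0.162, p = 0.41 by camera), with 2-fold (0.065) or 8-fold (0.036) sets, or without the dimmest clusters (0.181). Without single arrays it lay between 0.13 and 0.194, and it did not pass without stroma close to follicles replicate 1 (0.133) or 2 (0.13) or tunica albuginea replicate 1 (0.166) or 4 (0.142). Against interstitial stroma the difference of 0.041 was -0.006 and -0.042 with the 2-fold and 8-fold sets, and lay between -0.035 and 0.09 without single arrays. Of 147 list tests, camera called 72, and 8 with an estimated correlation; fry called 82, the mean over clusters 73, the replicate block 72 and the filter 59, and leaving out single arrays gave 69 to 76. Signals near background limit the dim genes.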

Other observations

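The test of granulosa genes in stroma close to follicles, that of expression by stromal cells, that of the brighter microRNA genes, that of the whole granulosa list across theca arrays and that of the granulosa list without INHA, INHBA and FST were chosen only after the result was seen. The genes MIR29C, MIR21, MIR143, MIR145 and FOXL2 were chosen after their values were seen.

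Other splits of the same arrays were tested for each count of changed clusters. For theca, chance can be excluded if arrays are independent, since 1 of 100 splits, the real one, reached the real count in each case. The real counts were 7747 against interstitial stroma (highest other split 3684), 8314 against stroma close to follicles (1221), 9207 against tunica albuginea (4331), 11206 against the mean (4028) and 9743 in the F test (3467). For tunica albuginea, 1 of 35 splits reached the real count, which is the real split and the smallest share possible. The counts were 407 against interstitial stroma (highest other 4) and 1017 against stroma close to follicles (highest other 4). With 35 splits the share cannot fall lower, so chance is argued against there only at that level and on the same condition. Whether pools shared animals is not given. The condition is in doubt for tunica albuginea against interstitial stroma, whose arrays of equal replicate number correlated at 0.095 to 0.145 after group means were removed. For stroma close to follicles against interstitial stroma, 3 of 35 splits gave at least the real 9 clusters, and chance cannot be excluded. The highest other split gave 33 clusters, with stroma close to follicles replicate 3 placed beside interstitial stroma replicates 1, 2 and 4. Another gave 18, with interstitial stroma replicate 1 placed beside stroma close to follicles replicates 1, 2 and 4. Both splits exchange 1 array of each compartment and leave the others in place. Stroma close to follicles replicate 3 changes sides with interstitial stroma replicate 3 in the first, and with interstitial stroma replicate 1 in the second. Both call more clusters than the real split, so the count depends on where single arrays are placed. The cause was not tested.

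Germ cell genes tended to be higher in stroma close to follicles than in interstitial stroma, but the list's call was lost with an estimated correlation (adjusted p = 0.099 by camera), and the difference in its means did not pass 0.05 (exact permutation p = 0.0571). The oocyte list stood at 4.82, 5.07, 3.93 and 4.09 in the 4 arrays close to follicles, at 3.66 to 4.03 in interstitial stroma and at 3.19 to 3.43 in tunica albuginea, with the abundant genes DAZL at 7.08 and ZP3 at 6.10 on average close to follicles. Oocytes captured with the stroma are a candidate source, since the list's genes moved together within compartments. Their mean correlation was 0.47 across genes and 12 arrays, against an upper limit of 0.09 for random lists of like brightness. Of the 15 genes, 4 lay above the median signal in interstitial stroma. The fixed lists shared no measured members, which says nothing on where these genes are expressed. Granulosa cells captured as well cannot be told apart from none, since their list differed by 0.1 with a 95% interval of -0.06 to 0.26. The interval includes 0.16, a cut-off taken as a set share of the oocyte difference in the same arrays. How much captured follicle cells would raise the list is not known from these data. Expression by the stromal cells themselves also cannot be told apart from captured oocytes, because both give the oocyte difference of 0.66.

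MicroRNA genes were lower in theca, with 183 of 528 lower and 48 higher and a median of -0.2. MIR99A fell by 3.83, and MIRLET7C (-3.62), MIR29C (-3.40), MIR21 (-3.28), MIR143 (-2.31) and MIR145 (-2.17) were lower. Lists of like brightness had medians of -0.12 to -0.07, so on these arrays the microRNA genes lay lower than genes of like brightness. That range comes from redrawing genes and not arrays, and takes no account of genes that move together. It therefore cannot decide whether a shift of all dim genes is the whole source. A loss of short RNA with the column kit cannot be told apart from other sources: the 126 brighter microRNA genes had a median of -0.02 within the range of like lists (-0.1 to 0.12), but their clusters can also read longer host transcripts. Among laser-captured compartments, which shared a kit, 2 of the 3 comparisons also lay outside the range of like lists. Tunica albuginea had medians of 0.1 against interstitial stroma (0 of 528 genes changed) and 0.08 against stroma close to follicles (2 higher, 2 lower). Both medians are no larger than the rounding step of 0.1, and the class had a mean level of 3.4, below the median signal. The range comes from redrawing genes and not arrays, so this test cannot decide whether the compartments themselves differ.

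Granulosa markers were called higher in theca (lost at adjusted p = 0.12 with an estimated correlation, camera), where FST stood at 7.23, INHA at 7.52 and INHBA at 7.60, while FSHR and AMH were both at 4.38 and CYP19A1 at 2.98. FOXL2 had a log2 difference of -0.51. Granulosa cells carried along with the dissected theca cannot be told apart from expression by theca, which was not tested: the higher genes had a mean correlation of 0.09 across the 6 theca arrays, between the median of random like lists (-0.01) and their upper limit (0.19). All 14 members gave 0.07, against an upper limit of 0.12, although FSHR (4.7 to 5.4 against 3.4 to 4.1) and CDH2 (5.0 to 6.3 against 3.1 to 3.3), a pair chosen after its values were seen, were both higher in theca replicates 1, 3 and 6 than in the others. Of the 14 genes, 5 lay above the median signal in interstitial stroma. None was a member of another list, which held for all the fixed lists and says nothing on where these genes are expressed. Whether INHA, INHBA and FST alone make up the shift cannot be decided, because the tests of the other 11 genes differ. Their median of 0.3 lay above the range of like lists (-0.28 to 0.22), with 6 genes higher in theca and 2 lower. Camera did not call these 11 genes as a set of their own.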
